A study of Mus musculus with 2 samples.

How the data were processed

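The data are the authors' deposited tables of single-nucleus RNA sequencing of mouse hippocampus, with 1 table for each of 9 cell types and 1 comparison, the GWI library against the control library. Per the labels' protocols, nuclei were isolated with a tissue dissociator, captured with the 10x Genomics 3′ v3.1 chemistry and sequenced to at least 25000 reads per nucleus. Per the submitters' processing notes, Cell Ranger and the mouse build GRCm38 (mm10) were used, with no version given. The program that grouped nuclei into cell types, the treatment of doublets and free RNA, and the test behind the tables are not given in the sources used here. The cell type of each table is the authors' own annotation.

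Each table gives 3 kinds of values made by the authors. The deposited log2 fold changes compare mean expression in the GWI library with that in the control library, per the file headers, and how the means were scaled and whether a pseudocount was added is not given in the sources used here. The deposited fractions of nuclei with the gene detected, 1 for each library, are printed here as percentages. The headers number the groups without naming them, so the first was taken to be GWI from the order of names in the comparison label, and every direction given here rests on that reading. That label writes PBS where the library names write vehicle, and these were taken to be the same libraries. The deposited p-values were computed by the authors over nuclei, and their adjusted p-values equal the raw ones times 25706 in every table. Nuclei of 1 library are not replicates, so these p-values were not used. Every listed gene was detected in at least 10% of the nuclei of 1 library and had an absolute log2 fold change of at least 0.05, so genes that differed less are not analysed here and a list's median covers listed members only.

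Each group is 1 library of 3 pooled mice. No test, standard error or count of significant genes was therefore computed, and genes were described by a fixed rule of size, an absolute log2 fold change of at least 1. Molecules per nucleus and the number of nuclei per table are not given in the sources used here, and no interval is given for a difference between the libraries. The genes named were chosen by a rule written before the data were examined: the 5 highest and 5 lowest log2 fold changes of each table, 12 and 12 in microglia, leaving out predicted genes, Riken clones and mitochondrially encoded genes, then up to 4 members with the largest change of each list described, any listed member of 6 immune lists in microglia, and the cholinesterase, muscarinic receptor and sodium channel genes in neurons. Genes named outside that rule, which are those listed in all 7 tables and further members of described lists, were chosen after their values were seen.

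The 51 gene lists, among them 11 lists of cell type markers, were written before the data were examined. A list with at least 3 listed members was described by its median and by that median's percentile among 10000 random lists of the same size, matched on the decile of mean detection, with a fixed seed. The ribosomal list was defined by a name pattern that also took in ribosomal S6 kinases, and these were removed after the results had been seen. Random lists matched also on gene length, in 5 length and 5 detection bins for every list and in 10 length and 2 detection bins for 4 microglial lists, were added after the data were examined. Spearman correlations are across genes within these libraries, and genes are not independent replicates. The 7 tables set beside one another leave out endothelial cells and pericytes, a choice made after the wider spread of those 2 was seen. Gene positions, lengths and GC content came from the GENCODE M21 annotation of GRCm38, in which 98.5% of the 10596 symbols were found.

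The percentile step was tested on simulated lists of 15 genes with a planted shift, after the values of the real tables were shuffled among genes of the same detection decile. Shuffling removes the trend with gene length, so these counts do not give the error rate of the real lists. In microglia, with 2534 genes, 8 of 200 lists with no shift, 52 of 200 with a shift of 0.1 and 182 of 200 with a shift of 0.3 lay in the upper tail of random lists. In pericytes, with 2613 genes and a wider spread, these numbers were 5, 10 and 70, so that most lists shifted by 0.3 would be missed there. A first run of 100 lists fell short of what this test was set to recover in microglia, after which more lists were simulated and that requirement was lowered.

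Other settings chosen before the data were examined were centring on the median of each table, subtracting each gene's median change in the other cell types, a detection minimum of 25%, no detection minimum, the mean in place of the median, and a size rule of 0.5. Analyses used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.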

Results

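Nuclear RNA was profiled in the hippocampus of aged male mice by droplet-based single-nucleus sequencing of transcript 3′ ends. At 10 weeks of age the mice had received daily intraperitoneal injections for 10 days. One group was given pyridostigmine bromide at 0.7 mg/kg, a carbamate that inhibits cholinesterases, with permethrin at 200 mg/kg, a pyrethroid that acts on voltage-gated sodium channels. The other group was given vehicle. The strain is given as C57BL/6J for all mice in the series description, but the genotype label reads C57/BL7 for the GWI library and C57/BL6 for the control library, which was taken as a slip and cannot be checked here. The chemicals model Gulf War Illness, and the exposed group is called the GWI group here. The mice were killed at 19 months, and the hippocampi of 3 mice per group were pooled into 1 library, which gave 1 control library and 1 GWI library. The labels state a depth of at least 25000 reads per nucleus. The number of nuclei per cell type and the molecules per nucleus are not given in the sources used here, and no interval is given for any difference between the libraries.

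The comparison asks how gene expression in each hippocampal cell type of the old mouse differed after the early exposure, with microglia, the resident immune cells of the brain, as the main interest of the study's title. The authors deposited a table for each of 9 cell types, with the log2 fold change of the GWI library over the control library for each gene and the percentage of nuclei in which it was detected. With 1 library per group there is no replicate spread and no test, so all differences below are between these 2 libraries, and no gene is called changed. An absolute log2 fold change of at least 1 was reached by 3 genes in microglia, 0 in excitatory neurons, 4 in inhibitory neurons, 1 in oligodendrocytes, 2 in astrocytes, 71 in oligodendrocyte precursor cells (OPCs) and 30 in the group named Other. The endothelial and pericyte tables held 864 and 580 such genes, and their log2 fold changes spread more widely, with a standard deviation across genes of 0.80 and 0.96 against 0.26 in microglia. These counts include predicted genes, Riken clones and mitochondrially encoded genes. The ranked genes below leave those out, and some of those left out had larger changes than the genes named.

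In microglia, genes of lysosomal proteases and complement were among those higher in the GWI library. Ctsl, which encodes the protease cathepsin L, had the highest value among the ranked genes of the authors' deposited table, a log2 fold change of 1.32. It was detected in 25.8% of GWI nuclei against 10.8% of control nuclei. Cst3, which encodes the cathepsin inhibitor cystatin C, was 1.96-fold higher and was detected in 74.8% against 56.0% of nuclei. The tetraspanin genes Cd9 and Cd81 were higher by log2 fold changes of 0.99 and 0.92, but Cd9 was also higher in oligodendrocytes (0.80), OPCs (1.09) and endothelial cells (2.25) and went to -0.10 once the change in other cell types was subtracted. The same subtraction left Ctsl at 0.78, Cst3 at 0.63 and Cd81 at 0.49. The complement C1q subunit genes C1qc, C1qa and C1qb were higher by 0.84, 0.75 and 0.32, and C1qc was detected in 61.6% against 42.5% of nuclei. Fcer1g, which encodes the common signalling chain of Fc receptors, was higher by 0.80. The other genes among the 12 highest ranked were Mir142hg (1.07), Etv5 (0.92), Zc3h6 (0.90), Tmed9 (0.84), Ppib (0.77) and Ssbp1 (0.77). Of the 3 genes past the size rule, only Ctsl and Mir142hg were among the ranked genes.

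In GRCm38 coordinates, Ctsl lies on chromosome 13 from 64359337 to 64370890 on the minus strand, Cst3 on chromosome 2 from 148871722 to 148875692 on the minus strand, and C1qc on chromosome 4 from 136889804 to 136893065 on the minus strand. All 3 are annotated as protein-coding genes.

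**Figure D1:**
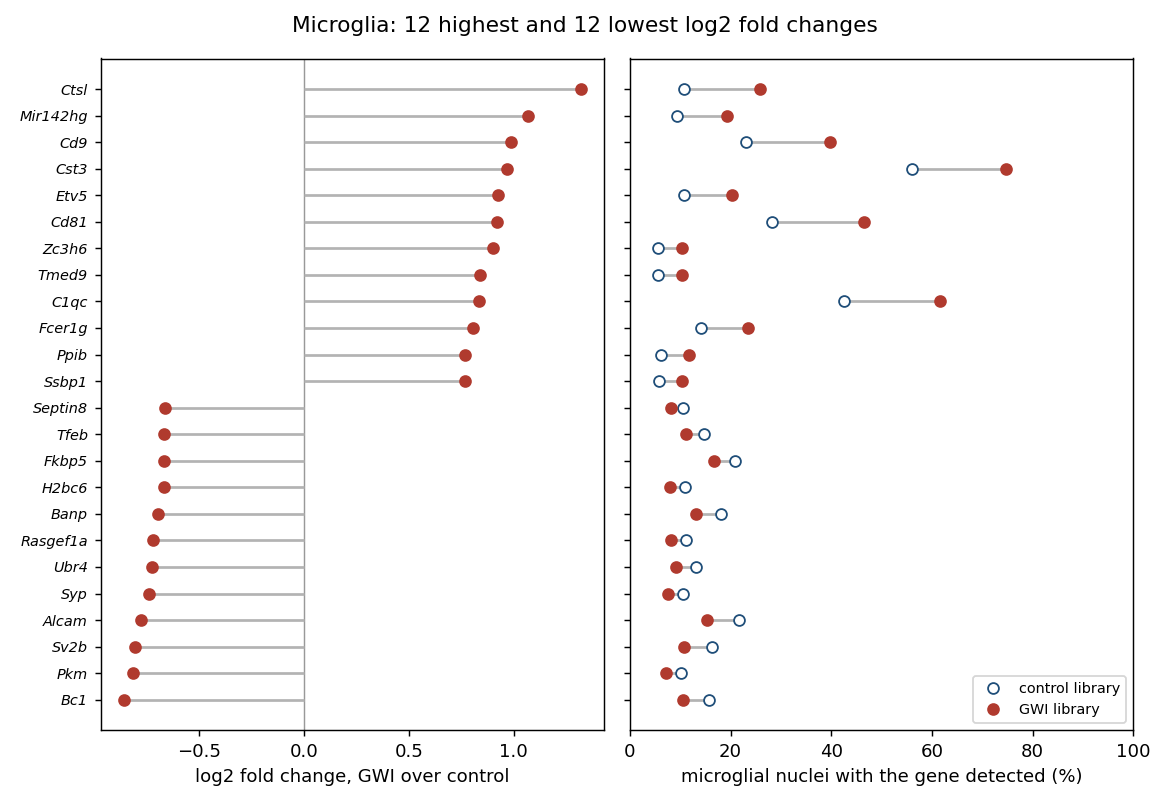
The left panel plots the log2 fold change of the GWI library over the control library for the 12 highest and 12 lowest ranked genes of the microglia table. Predicted genes, Riken clones and mitochondrially encoded genes are left out. The right panel plots the percentage of microglial nuclei in which each gene was detected, with open points for the control library and filled points for the GWI library. Of the genes plotted, Ctsl is highest at 1.32 and Bc1 lowest at -0.86. Each point is 1 library of 3 pooled mice, so no error bars can be drawn.

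Gene lists fixed beforehand hold many of these genes. Of 15 listed homeostatic microglia genes, 12 were higher in the GWI library, with a median log2 fold change of 0.24, above all 10000 random lists of equal size and detection. They included the purinergic receptor gene P2ry12 (0.55), Gpr34 (0.65) and Tmem119 (0.37), while Mertk (-0.32), Bin1 (-0.30) and Sall1 (-0.15) were lower. Of 11 listed genes of disease-associated microglia, 9 were higher, with a median of 0.27, among them Ctsz (0.44), Ctsb (0.33), Ctsd (0.33) and Trem2 (0.23), and the median was 0.16 once the change in other cell types was subtracted. All 6 listed complement genes were higher, with a median of 0.32, above 99.81% of random lists. Of 15 lysosomal and phagocytic genes 11 were higher, with a median of 0.27, including Ctss (0.63), Lamp1 (0.61) and Laptm5 (0.49), whereas Tfeb, which encodes a transcription factor for lysosomal genes, was lower at -0.67. The homeostatic, disease-associated, complement and lysosomal lists had median gene lengths of 22.0, 12.1, 7.54 and 25.6 kb, though some members are longer, and short genes were higher in most tables. Against random lists also matched on gene length, in a comparison added after the data were examined, the complement list lay at 94.2% and the homeostatic, disease-associated and lysosomal lists at 98.18%, 98.56% and 98.9%. With 10 length and 2 detection bins in place of 5 and 5, the homeostatic, disease-associated and complement lists lay at 96.32%, 97.05% and 95.87%, and the lysosomal list at 98.9%.

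Inflammatory and immune-restraint genes of microglia stood apart less. Of 5 listed inhibitory checkpoint genes 4 were higher, with a median of 0.08 at 69.7% of random lists, or 25.7% when gene length was matched as well. Havcr2, which encodes the checkpoint receptor TIM-3, had the highest value at 0.34, followed by Vsir (0.09), Tgfb1 (0.08) and Cd300a (0.05), with Il10ra at -0.06. Of 5 genes of the inflammatory NF-kB list 3 were higher, with a median of 0.11 at 69.6%, with Tlr4 at 0.38, Tlr7 at 0.11, Hmgb1 at 0.11, Rel at -0.09 and Nfkb1 at -0.20. Among genes of cGAS-STING and JAK-STAT signalling 6 of 8 were higher, with Il6st at 0.69, Ifngr1 at 0.54, Ifnar2 at 0.21 and Il6ra at -0.16, and with a median at 95.9% of random lists, or 81.6% with gene length matched. Of the interferon response list Trim30a alone was listed (-0.23), and of the antigen presentation list H2-K1 (0.59) and B2m (0.22).

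Genes lower in GWI microglia included many that neurons express. Bc1, a neuronal noncoding RNA, had the lowest value among the ranked genes at -0.86, followed by Pkm (-0.82), Sv2b (-0.81), Alcam (-0.78), Syp (-0.74), Ubr4 (-0.73), Rasgef1a (-0.72), Banp (-0.70), H2bc6 (-0.67), Fkbp5 (-0.67), Tfeb (-0.67) and Septin8 (-0.66). Of 12 listed synaptic vesicle and adhesion genes 1 was higher, with a median of -0.22, or -0.11 once the change in other cell types was subtracted, and of 13 glutamate receptor genes 3 were higher, with Gria3 at -0.49 and Grm5 at -0.38. Markers of other cell types were lower in 10 of 11 cases, with a median of -0.20, while 5 of 6 microglial markers were higher, with a median of 0.45.

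In excitatory neurons, genes of ribosomal proteins, glycolysis and calcium signalling were lower in the GWI library. Of 31 listed ribosomal protein genes 7 were higher, with a median log2 fold change of -0.15, below all 10000 random lists, and Rpl13 (-0.34) and Rps15 (-0.33) were the lowest. Of 14 glycolysis genes 2 were higher, with Pfkfb3, which encodes a regulator of glycolytic flux, at -0.74 and Pkm at -0.33. Of 17 calcium signalling genes 2 were higher, with the channel subunit genes Cacna2d2 at -0.62 and Cacna1h at -0.49. The highest ranked genes in the authors' deposited table were Ptgds (0.98), Hs3st1 (0.71), Rassf3 (0.70), Nrg3os (0.68) and Sorbs2os (0.67), and the lowest ranked were Rhbdl3 (-0.76), Gng7 (-0.76), Pfkfb3 (-0.74), Dpysl5 (-0.73) and Prkch (-0.70). Once the median change in the other cell types was subtracted, the medians were -0.086 for ribosomal protein genes, -0.014 for glycolysis and 0.028 for calcium signalling. Inhibitory neuron markers were lower in excitatory neurons, with Gad2 at -0.53 and Gad1 at -0.45.

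Of the exposure's known targets, some cholinesterase, muscarinic receptor and sodium channel genes were listed in neurons in the authors' deposited tables. Of the sodium channel genes, Scn1a and Scn2a had log2 fold changes of 0.09 and 0.10 in excitatory neurons and 0.07 and 0.10 in inhibitory neurons, Scn8a was at -0.05 and -0.11, and Scn3a was at 0.27 in inhibitory neurons. The muscarinic receptor gene Chrm3 was at 0.26 in excitatory and -0.06 in inhibitory neurons, and Chrm2 at 0.07 and -0.12. Ache, which encodes acetylcholinesterase, was at 0.50 in inhibitory neurons, where it was detected in 10.1% against 8.2% of nuclei.

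In inhibitory neurons, interneuron peptide genes were higher and immediate early genes lower in the GWI library in the authors' deposited table. Vip, which encodes vasoactive intestinal peptide, was 3.23-fold higher and was detected in 10.3% against 5.7% of nuclei, and Npy, which encodes neuropeptide Y, was 1.96-fold higher and was detected in 24.5% against 16.1%. All 7 listed inhibitory neuron markers were higher, with a median of 0.31, including Slc32a1 (0.34) and Sst (0.31). Of 5 immediate early genes 1 was higher, with a median of -0.37, and Nr4a3, an activity-induced nuclear receptor gene, had the lowest value of the table at -2.20, detected in 4.8% against 11.6% of nuclei. Of 20 synaptic vesicle and adhesion genes 5 were higher, with a median of -0.23, including Homer1 at -0.49 and Shank1 at -0.41. Once the median change in the other cell types was subtracted from each gene, the synaptic median was 0.034 and the immediate early median -0.095. The remaining named genes were Tmed4 (1.03), Bmyc (0.99) and Nrg3os (0.82) among the highest, and Zfp423 (-0.73), Zbtb7c (-0.70), Ppard (-0.68) and Stac (-0.68) among the lowest.

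In oligodendrocytes, myelin and lipid genes were higher in the GWI library in the authors' deposited table. Of 16 listed myelin genes 13 were higher, with a median log2 fold change of 0.22, including the prostaglandin D synthase gene Ptgds (0.57) and Ermn (0.49). The median lay above all random lists matched on detection and at 93.7% of those also matched on gene length. Of 5 listed oligodendrocyte markers 3 were higher, with a median of 0.06, and the other markers Mbp and Mobp were at -0.08 and -0.11. Of 4 listed cholesterol and lipid genes 3 were higher, with a median of 0.42 at 99.98% of random lists, or 0.18 once the change in other cell types was subtracted: the desaturase genes Scd1 (0.54) and Scd2 (0.46) and Apoe (0.38), with Srebf2 at -0.10. Synaptic and calcium genes were lower, with 1 of 14 synaptic vesicle and adhesion genes and 1 of 18 calcium signalling genes higher. Markers of neurons and astrocytes were mostly lower with them, such as Camk2a (-0.49), Grin2b (-0.33) and Slc1a2 (-0.36), but Prox1 was at 0.14. The extremes among the ranked genes were Evi2a (0.81), Cd9 (0.80), Pmp22 (0.74), Shisa4 (0.70) and Degs1 (0.69), and Bfsp2 (-1.11), P4ha1 (-0.81), Hspa4l (-0.70), Caln1 (-0.67) and Pde7b (-0.65).

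In OPCs, all 6 listed cholesterol and lipid genes were higher in the GWI library in the authors' deposited table, with a median of 0.40, above 99.7% of random lists. They included the cholesterol exporter gene Abca1 (0.52), detected in 61.4% against 43.3% of nuclei, and Srebf1 (0.43), which encodes a transcription factor for lipid synthesis genes. Cd9 was higher by 1.09 and the tetraspanin gene Cd63 by 0.88, and the lineage genes Olig2 and Olig1 by 0.66 and 0.51. The OPC identity list as a whole stood apart less, with 10 of 14 genes higher and a median of 0.078 at 91.7% of random lists, and Pdgfra was at 0.06 and Cspg4 at -0.15. Markers of other cell types went both ways in OPCs, with the astrocyte marker Aqp4 at 1.21 and the neuronal markers Camk2a at -0.55 and Gad2 at -0.88. Among the ranked genes, Slc7a1 was highest at 3.73-fold, followed by log2 fold changes of 1.83 for Agbl3, 1.81 for Vstm5, 1.68 for Atp6v0e2 and 1.62 for Ap1s2. The lowest log2 fold changes among them were those of Rpl10a (-2.07), Lgi2 (-1.54), Uchl1 (-1.47), Smarcd3 (-1.34) and Cabp1 (-1.33). Of the 71 genes with an absolute log2 fold change of at least 1, 69 were detected in fewer than 25% of nuclei of both libraries.

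In astrocytes, homeostatic genes were higher and calcium signalling genes lower in the GWI library in the authors' deposited table. Of 15 listed homeostatic genes 13 were higher, with a median of 0.17, including the water channel gene Aqp4 (0.47), Clu (0.45) and the gap junction gene Gja1 (0.35). The median lay above 99.88% of random lists and at 96.8% of those also matched on gene length. Of 13 cholesterol and lipid genes 11 were higher, with Insig1 at 0.35 and Srebf1 at 0.32. All 17 listed calcium signalling genes were lower, with a median of -0.20, as were all 8 mitochondrially encoded genes, with a median of -0.22. Once the change in other cell types was subtracted, the medians were -0.010 for calcium signalling and 0.036 for cholesterol and lipid genes. The inhibitory neuron markers Gad2 and Gad1 were at -0.69 and -0.63. Several excitatory neuron markers were detected in many astrocyte nuclei, with Grin2b in 77.5% of GWI against 80.0% of control nuclei. Camk2a was in 62.2% against 63.4% and Slc17a7 in 47.8% against 47.9%, but Neurod6 only in 10.0% against 9.4%. How much of this table's change comes from neuronal RNA was not tested. The extremes among the ranked genes were Dynlt2a2 (0.77), Pwwp3a (0.74), Hsdl2 (0.72), Mitd1 (0.71) and Pax6 (0.66), and Cbfa2t3 (-0.94), Alk (-0.87), Nkain3 (-0.82), Bc1 (-0.76) and Htr2c (-0.74). The 1 higher and 1 lower gene of this table past the size rule are among those left out of the ranking.

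In endothelial cells, antigen presentation genes were higher, and mural cell and haemoglobin genes lower, in the GWI library in the authors' deposited table. All 5 listed antigen presentation genes were higher, with a median of 0.86, above 99.8% of random lists, including the class I genes H2-K1 (0.91) and H2-D1 (0.86) and the immunoproteasome gene Psmb9 (2.59), which was detected in 10.7% against 1.1% of nuclei. All 10 listed pericyte and mural genes were lower, with a median of -0.71, including Notch3 at -1.47 and Vtn at -0.89. The haemoglobin genes Hbb-bt, Hba-a1, Hba-a2 and Hbb-bs were at -4.73, -4.69, -4.54 and -3.87. Lcp1, detected in 10.7% of GWI nuclei, was listed at 0 in the control library. Other extremes among the ranked genes were log2 fold changes of 4.69 for Fmo5, 4.63 for Caskin2, 3.76 for Mcoln1 and -4.70 for Ddx31. Hmgb2, also among them, was 14.0-fold higher.

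In pericytes, 17 synaptic vesicle and adhesion genes were listed in the authors' deposited table and 1 was higher in the GWI library, with a median of -0.58, and 2 of 11 potassium channel genes were higher, with Kcnd3 at -3.23 and Kcnb2 at -3.00. The mural list had 11 of 14 genes higher, with a median of 0.19 at 87.0% of random lists, with Mcam at 1.82, Rgs5 at 0.76 and Pdgfrb at 0.60, while Myh11 was at -1.54. Tmem109, Vasp, Ubxn2a and Phyh were listed at 0 in the control library and Ube2j2 at 0 in the GWI library. Tomm34, Sestd1, Ntng1 and Chchd2 had the next lowest values among the ranked genes, at -4.14, -3.81, -3.59 and -3.53.

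In the group named Other, 53 ribosomal protein genes were listed in the authors' deposited table and 13 were higher in the GWI library, with a median of -0.18, below all 10000 random lists, with Rps15 at -0.82. With detection in at least 25% of nuclei that median turned to 0.16. Among the ranked genes, log2 fold changes were highest for Rnf17 (1.31), Rab9b (1.22), Mrpl55 (1.17), Vwc2l (1.13) and Gfpt2 (1.12). Kcnip2 was the lowest of them, 2.47-fold lower, followed by log2 fold changes of -1.19 for Pcdha11, -1.18 for Ptpru, -1.15 for Hpcal1 and -1.13 for Supt7l.

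**Figure D2:**
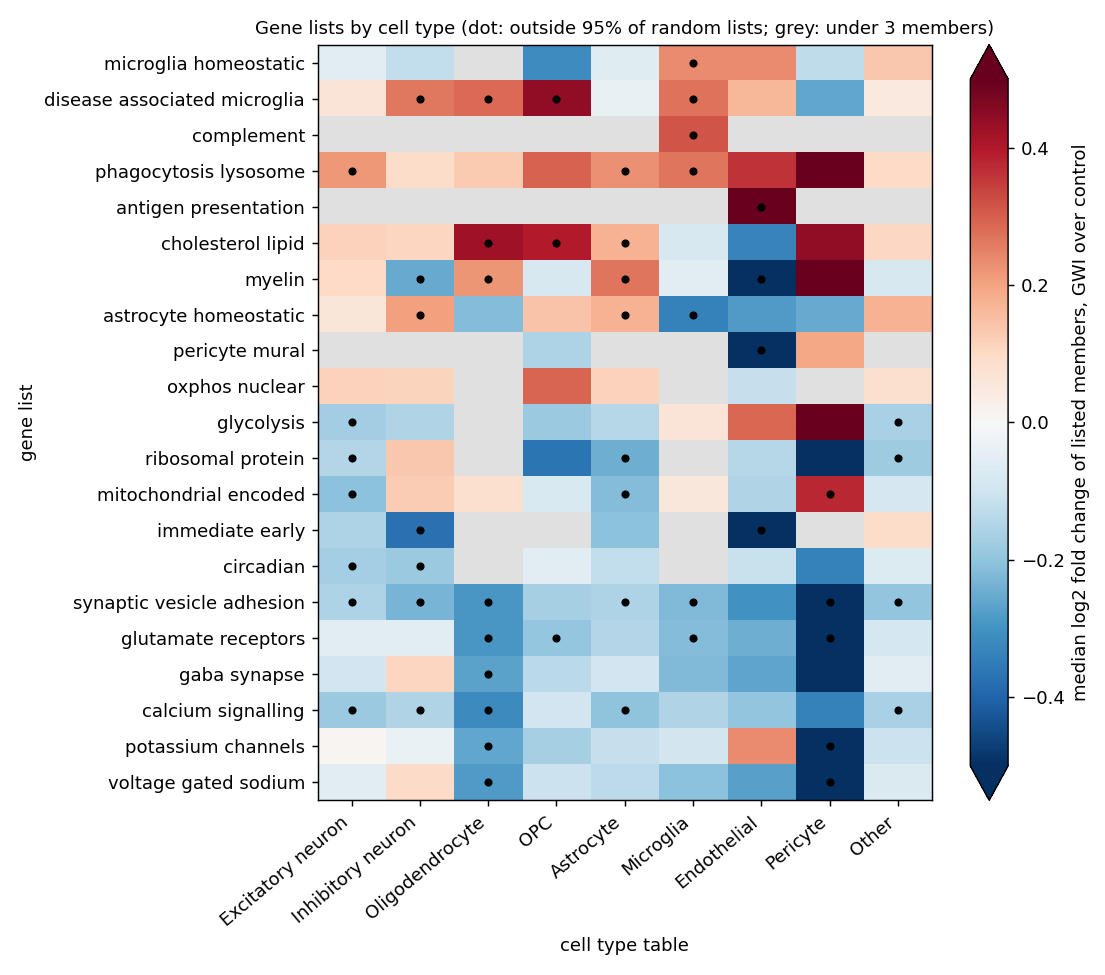
Each cell shows the median log2 fold change, GWI over control, of the listed members of 1 gene list in 1 cell type table, on a colour scale cut at -0.5 and 0.5, and a dot marks a median in either outer tail of random lists matched on detection. Grey cells had fewer than 3 listed members. Synaptic vesicle and adhesion genes are on the lower side in all 9 tables, with medians such as -0.22 in microglia and -0.23 in inhibitory neurons, but 4 of these medians turned direction once the change in other cell types was subtracted.

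Over 51 lists and 9 tables, 298 medians could be placed among random lists. Of these, 23 lay in the upper and 53 in the lower tail of random lists, against 14.9 in both tails together if lists behaved as random draws, though lists share members and the same 2 libraries enter every table. Matched also on gene length, 18 and 53 did so, and 15 and 45 lay in the tail under both matchings.

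The change per gene was alike in many cell types. Across genes, the Spearman correlation of the log2 fold changes had a median of 0.50 over the 21 pairs of the 7 tables other than endothelial cells and pericytes, with a range from 0.30 to 0.76, and a median of 0.13 over the 15 pairs that include either of those. Of 456 genes listed in all 7 tables, 104 were higher and 160 lower in all 7, against 1.1 and 9.7 if the tables were independent, which tables of the same 2 libraries are not. The lysosomal membrane gene Lamp1 had the highest median over these tables at 0.54, followed by Itm2b (0.49), Rsrp1 (0.49), Cd81 (0.48) and Ppib (0.41), and the nuclear RNA Malat1 was at 0.37, while the mitochondrially encoded mt-Nd5 (-0.36) and mt-Co1 (-0.11) were lower in all 7. Bc1 had the lowest median at -0.60, followed by Banp (-0.45), Gse1 (-0.44) and Map1a (-0.43). Ctsl was also higher in excitatory neurons (0.48), inhibitory neurons (0.72), OPCs (0.56) and astrocytes (0.52), and Cst3 in those 4 tables by 0.12 to 0.49.

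Shorter genes were higher and longer genes lower in the GWI library in the 7 tables and in pericytes. In microglia, the fifth of genes with the shortest span had a median log2 fold change of 0.16 and 69.0% were higher, while the fifth with the longest span had a median of -0.13 and 26.2% were higher. Across genes, the Spearman correlation of the change with gene length ranged over the 7 tables from -0.18 in Other to -0.51 in oligodendrocytes. It was -0.33 in microglia, -0.17 in pericytes and -0.02 in endothelial cells.

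**Figure D3:**
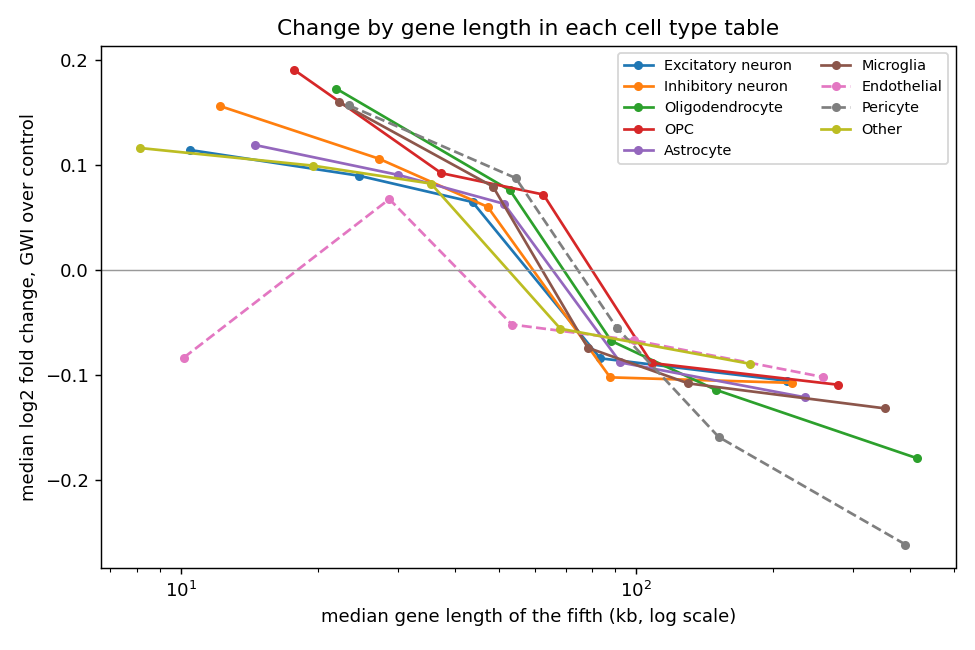
Lines show, for each cell type table, the median log2 fold change of the GWI library over the control library in 5 equal groups of genes ordered by length, against the median gene length of each group in kilobases on a log axis. Dashed lines are endothelial cells and pericytes. In microglia the median goes from 0.16 in the shortest group to -0.13 in the longest.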

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

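The tests of gene length in the microglial lists, of retained cytoplasm, of free RNA in astrocytes and OPCs, of 5 microglial genes set against other cell types, and of interneuron subtypes and hippocampal subregions were chosen only after results had been seen, as was the microglial pattern itself.

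Several gene lists lay among the highest medians in 1 cell type and among the lowest in another, and none of these differences was tested, because each group is 1 library. Inhibitory neuron markers had a median log2 fold change of 0.31 in inhibitory neurons and -0.58 in astrocytes, a difference of 0.89. Myelin genes had a median of 0.27 in astrocytes and -1.21 in endothelial cells, a difference of 1.47. Homeostatic astrocyte genes had a median of 0.20 in inhibitory neurons and -0.34 in microglia, a difference of 0.54, but the first turned to -0.0079 with detection in at least 25% of nuclei. Mitochondrially encoded genes had a median of 0.38 in pericytes and -0.22 in astrocytes, a difference of 0.59.

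The change per gene was alike in 7 tables, for which free RNA of neurons entering all droplets is a candidate explanation. The test planned for it, in genes detected more often in astrocytes and microglia than in excitatory neurons, gave a Spearman correlation of 0.64 but held only 23 of the 50 genes it required, so it decided nothing. In astrocytes and OPCs, the only 1 of 4 pairs with enough genes, 55 such genes gave 0.53, with bounds of 0.25 and 0.72 from resampling genes. That met the bounds set against free RNA of neurons, which were written after the first test had been seen. But every gene tested was also listed in excitatory neurons, and inhibitory neurons were not checked, so the test cannot exclude neuronal RNA as the source. The other 2 pairs gave 0.67 over 25 genes and 0.24 over 12. Centring within bins of detection left the median correlation at 0.43 from 0.50, so detection level was not the whole source, while centring within bins of gene length and GC content took it to 0.34 from 0.50, which leaves part of the pattern tied to length or GC content and cannot be told apart further. An exposure effect on all cell types and free RNA of neurons or other cells remain open. So does any difference in how the 2 libraries were made, nuclear purity included, since each group is 1 library.

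In microglia, cathepsin, cystatin, tetraspanin and complement genes were higher in the GWI library. A lower share of free RNA would raise genes of microglia by about 1 factor, but 28.8% of 52 such genes lay below 0, which argues against it as the whole cause, although a mixture of free RNA with the trend in gene length was not tested. Gene length cannot be told apart from the pattern: with 10 length and 2 detection bins the lowest of the homeostatic, disease-associated and lysosomal lists lay at 96.32% of random lists and the complement list at 95.87%, between the bounds set for either outcome, while with 5 length and 5 detection bins the same 3 lists lay at 98.18%, 98.56% and 98.9%. A class of secretory and membrane transcripts may also be involved, since short genes of that class exceeded other short genes by at least 0.1 in 2 of 6 other tables, and retained cytoplasm was left undecided by a median of 0.063 over 13 mitochondrially encoded, ribosomal and glycolytic genes that went both ways, a test that had excluded it, at -0.082 over 18 genes, until S6 kinases were left out after the result was seen. For an effect of the exposure on microglia, the median of 0.61 over 9 genes of the pattern, after subtracting their change in other cell types, does not count, because 4 of them are listed in no other of these tables and nothing was subtracted, and the other 5 gave 0.45 from 0.97, were picked for the pattern and cannot be told apart from a library effect.

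Genes of some neuron subtypes stood apart from random lists. Genes of CA1 and CA3 pyramidal neurons did not, at 68.7% and 61.2% of random lists. A different mix of interneuron subtypes is a candidate explanation: with Vip and Npy left out because they had been seen, all 7 listed genes of caudal-ganglionic interneurons were higher, including Cnr1 (0.60), Penk (0.59) and Adarb2 (0.34), and their median of 0.34 lay above 99.99% of random lists, while 6 of 11 genes of medial-ganglionic interneurons were higher, with a median of 0.06 at 57.0%. A different mix of hippocampal subregions in the dissected tissue stays open, since dentate granule genes lay highest at 99.2%, with 7 of 10 higher, and the lowest of the 4 region lists lay at 61.2%. Whether the exposure altered interneurons themselves was not tested.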

How the results depend on the processing

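The settings chosen before the data were examined change the sizes of differences more than their directions, except that 2 list medians turned direction with detection in at least 25% of nuclei and 12 did where the change in other cell types was subtracted. No paired analysis was possible because each group is 1 library, and leaving out a replicate could not be run for that reason. The pseudocount alternatives were not run, because the tables hold fold changes. The alternative with no detection minimum moved nothing, since every listed gene already passed the minimum of 10%. Alternatives with unlisted members at 0 and with members whose detection goes the same way were added after the data were examined. So were those with only genes detected less in excitatory neurons and with matching on gene length. Of the list medians described, 17 were singled out after their values were seen. The causes of the differences below were not tested.

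With a size rule of 0.5, the counts were 129 in excitatory neurons, 145 in inhibitory neurons, 67 in oligodendrocytes, 728 in OPCs, 120 in astrocytes, 133 in microglia, 2375 in endothelial cells, 1369 in pericytes and 563 in Other. With detection in at least 25% of nuclei, the counts at the size rule of 1 were 0 in inhibitory neurons, oligodendrocytes and astrocytes, 2 in OPCs, 1 in Other, 77 in endothelial cells and 55 in pericytes. Of the genes named for the largest changes, 5 of 24 in microglia, 3 of 10 in excitatory neurons, and 1 of 10 in each of inhibitory neurons, oligodendrocytes and astrocytes kept their place at 25%, and 0 did in OPCs, endothelial cells, pericytes and Other. At 25%, the lysosomal list in microglia had a median of 0.47, the astrocyte list in inhibitory neurons -0.0079 from 0.20, and the ribosomal list in Other 0.16 from -0.18.

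Centring on each table's median gave 1 gene past the size rule in astrocytes and 5 in microglia, a median of 0.29 for myelin genes in oligodendrocytes and of -0.20 for ribosomal genes in excitatory neurons. Genes with an absolute log2 fold change under 0.05 are not listed, and most table medians lie just past that limit, such as -0.063 in microglia and -0.056 in astrocytes. The shift from centring therefore need not measure an offset between the libraries. The mean in place of the median gave 0.45 for complement genes in microglia and -0.64 for immediate early genes in inhibitory neurons.

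Subtracting the median change in the other cell types turned the direction of 12 list medians, while a gene listed in fewer than 2 other tables keeps its value under this setting. Synaptic vesicle and adhesion genes went to 0.085 in excitatory neurons, 0.034 in inhibitory neurons, 0.032 in astrocytes and 0.043 in Other. Calcium signalling genes went to 0.028 in excitatory and 0.062 in inhibitory neurons, lysosomal genes to -0.10 in excitatory neurons and -0.013 in astrocytes, ribosomal genes to 0.046 in astrocytes, and extracellular matrix genes to 0.075 in excitatory neurons. Oligodendrocyte stress genes in microglia went to -0.047 and OPC identity genes in inhibitory neurons to 0.0063. In microglia, Cd9 went to -0.10, the disease-associated list to 0.16 and the synaptic list to -0.11, while Ctsl stayed at 0.78 and Cst3 at 0.63. Glycolysis and ribosomal genes in excitatory neurons went to -0.014 and -0.086, and immediate early genes in inhibitory neurons to -0.095.

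With unlisted members at 0, medians became 0 for the disease-associated, complement, lysosomal and synaptic lists in microglia, antigen presentation in endothelial cells, immediate early genes in inhibitory neurons, cholesterol genes in OPCs and ribosomal genes in excitatory neurons, because unlisted members fill the middle of each list by construction. They were -0.078 for glycolysis and -0.11 for calcium signalling in excitatory neurons, -0.089 for synaptic genes in inhibitory neurons and -0.28 for mural genes in endothelial cells. Matched also on gene length, in 5 length and 5 detection bins, the complement list in microglia lay at 94.2%, myelin in oligodendrocytes at 93.73% and homeostatic genes in astrocytes at 96.84%; in 10 length and 2 detection bins the homeostatic, disease-associated and complement lists in microglia lay at 96.32%, 97.05% and 95.87%, and the lysosomal list at 98.9%. The median correlation between cell types was 0.44 for genes past the size rule in the 4 pairs with enough of them, all with OPCs, against 0.40 for all genes of those pairs. In the 4 pairs tested for free RNA, genes listed in excitatory neurons but detected less there gave 0.59. All genes of those pairs gave 0.54. The 0.50 over 21 pairs is not comparable with either.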

Other observations

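The tests of a secretory and membrane gene class and of genes with the name ending os were chosen after the data were examined.

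Among short genes, under 30000 bp, those whose protein has a predicted signal peptide or membrane helix were higher in the GWI library in more cases than other short genes in several tables. In microglia 84.9% of 139 such genes were higher, with a median log2 fold change of 0.30, against 64.3% of 241 others, with a median of 0.13. In oligodendrocytes the shares were 89.6% and 68.7%, and the difference of medians was 0.17 in both tables. The differences were 0.11 in OPCs, 0.08 in inhibitory neurons, 0.04 in excitatory neurons, 0.03 in astrocytes, -0.0056 in Other, 0.17 in endothelial cells and 0.27 in pericytes. Among genes of at least 30000 bp the difference was -0.012 in microglia and -0.0092 in oligodendrocytes, but 0.025 in inhibitory neurons and 0.015 in excitatory neurons, so it was not confined to short genes there. Both length classes were compared in all 9 tables.

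Genes whose names end in os, with or without a number, were higher in excitatory neurons. That ending marks transcripts on the strand opposite a neighbouring gene, but gene type was not checked, so protein-coding genes with the same ending can be included. Of 23 such genes 17 were higher, with a median of 0.32, above all 10000 random lists, including Nrg3os (0.68) and Sorbs2os (0.67). These random lists were matched on detection only, not on gene length. In astrocytes 10 of 16 were higher, with a median of 0.28 at 99.9% of random lists, and in Other 21 of 28, with a median of 0.24 at 99.8%. The medians stood apart less in inhibitory neurons (0.16 at 94.1%), OPCs (0.17 at 81.7%), microglia (0.10 at 79.0%), endothelial cells (0.38 at 91.4%), pericytes (0.19 at 75.2%) and oligodendrocytes, where 2 of 4 were higher.

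Circadian clock genes were lower in both neuron tables. Of 12 listed in excitatory neurons 2 were higher, with a median of -0.17 at 0.96% of random lists, Per2 at -0.36 and Per1 at -0.32, although Rorb was at 0.60. In inhibitory neurons 2 of 10 were higher, with a median of -0.19 at 1.01%, and Per1 and Per2 were both at -0.29. The hour of killing is not given in the sources used here.

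Genes of the disease-associated microglia list were higher outside microglia as well. The list had medians of 0.44 in OPCs, 0.28 in oligodendrocytes and 0.26 in inhibitory neurons, the lowest of these at 99.6% of random lists, with Cd63 at 0.88, 0.57 and 0.44 in those tables.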
